A study of Mus musculus with 2 samples.

How the data were processed

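MicroRNA (miRNA) levels were measured in 2 mouse RNA samples of the C57BL/6J strain, each on 1 single-colour Agilent miRNA array. One sample was whole bone marrow ("total BM"). The other was LKS cells, bone marrow cells that lack lineage markers and carry Kit and Sca1, a fraction that contains haematopoietic stem and early progenitor cells. Per the labels, RNA was extracted with the miRNeasy kit and labelled with Cy3 by Agilent's standard protocol. The LKS cells had been enriched on a magnetic column and then sorted by flow cytometry. With 1 array per group there was no replicate, so no p-value, SD or count of statistically changed miRNAs is given, and each difference below describes these 2 arrays.

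The authors deposited a table of linear signal intensity values, per the file headers the total gene signal of each probe set, with an error of each signal and a detection call of 0 or 1. These intensity values had been background-subtracted and not scaled between arrays: 315 of the 566 mouse miRNA names on the total BM array and 406 on the LKS array had signals below 0. The table holds 598 names, of which 566 were mouse miRNAs, 10 were viral miRNAs and 22 carried no miRNA identifier. The latter were treated as control probes, although the files do not define several of their names (hur, mr and dmr series). The authors also deposited a value table on a log2-like scale for the 576 miRNA names. Its values ranked every name as the raw signals did. They were fitted by an inverse hyperbolic sine of a linear function of the raw signal, divided by the natural log of 2, with largest residuals of 4.1e-09 on the total BM array and 3.4e-09 on the LKS array. Its scale is thus known, with column medians of 1.46 for total BM and 1.00 for LKS, but how the authors chose the constants is not given in the sources used here. The deposited detection call has only the values 0 and 1, and the rule behind it, the scanner and the extraction software are not given in the sources used here.

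Signals were divided by each array's 75th percentile over the 93 mouse miRNAs detected on both arrays, which was 399 on total BM and 242 on LKS, and log2 ratios were taken as LKS minus total BM. This raised every LKS to total BM ratio by 0.72 on the log2 scale relative to the signals as deposited. A miRNA was counted as higher or lower at a ratio of at least 2. The error given with a signal is the one in the deposited table. The error given with a log2 ratio was propagated from both signals, and it covers technical error on these arrays only. For a miRNA detected on 1 array only, the ratio is a lower bound ("at least N-fold"), with the brighter scaled signal over the dimmer array's own signal plus 2 of its errors, or over the lowest detected signal of that array if higher (1.01 on total BM, 2.91 on LKS). This floor was chosen after the data were examined, because on total BM the lowest detected signal alone lay below the median error of undetected probes (2.02) and gave larger bounds, such as 43.5-fold in place of 7.56-fold for miR-125b-5p. On LKS it lay above that error (1.91). Bounds such as those of miR-188-5p, miR-705, miR-144 and miR-150 are the same with either floor. Those of miR-451 and miR-801 were 17.3-fold and 49.8-fold, against 42.9-fold and 109-fold with the lowest detected signal alone. All bounds leave out the error of the brighter signal.

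The miRNA lists, the 2-fold rule, the scaling and the rule for named miRNAs were fixed before the data were examined. Named miRNAs were the 10 with the highest and the 10 with the lowest ratio among those detected on both arrays, the 5 brightest on each array, the up to 5 brightest detected on 1 array only, the up to 4 members of each list with the largest absolute log2 ratio, and 10 chosen beforehand (miR-125b, miR-125a, miR-155, miR-126, miR-196b, miR-223, miR-150, miR-451, miR-144 and miR-181a). Others, namely list members detected on 1 array only or on neither, names with no RefSeq gene, arm partners and genomic neighbours, were named after their values were seen. For a list with at least 3 members detected on both arrays, the median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean signal in 5 bins. The percentile describes these arrays and is not a test. A list was said to stand apart if it lay outside the central 95% of random lists.

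Names were matched to miRNA genes of a RefSeq table of the mouse assembly GRCm38.p6. Of the 566 mouse names, 547 matched a gene by symbol or synonym and 19 did not. The array files name no genome build, so no coordinates are given. On simulated arrays of 566 miRNAs, the counting recovered 20 of 20 detected 4-fold increases and 16 of 16 detected 4-fold decreases, and called 0 of 75 unchanged miRNAs, although scaling shifted the unchanged ones by a median of -0.24 on the log2 scale. The simulated changes were placed only in miRNAs bright on total BM. Detection was set by a fixed signal, and all probes were dimmed by 1 factor. The simulation therefore does not cover ratios from faint signals, such as that of miR-196b (9.78 in total BM), or unequal dimming. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6. Other scalings, filters, thresholds and the deposited value table were run as alternatives.

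The number of arrays limits the precision. Among detected miRNAs the median deposited error was 9.47% of the signal on total BM and 9.81% on LKS. On each array, 8 detected miRNAs had a signal under 3 times its error. Control probes were left out of the scaling and the counts.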

Results

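MiRNA profiles were obtained from total BM and from LKS cells of C57BL/6J mice, with 1 array each, to compare a fraction that holds early haematopoietic progenitors with whole bone marrow. Of 566 mouse miRNAs on the array, 145 (25.6%) were detected in total BM and 98 (17.3%) in LKS cells. Both arrays detected 93, total BM alone detected 52, LKS alone detected 5, and 416 were detected on neither. The LKS array was dimmer: its detected signals summed to 23256 intensity units against 52484 on total BM, and the median log2 ratio of the 93 shared miRNAs was -0.65 before scaling and 0.07 after it. Across these 93 miRNAs, which are not independent replicates, log2 signals of the 2 arrays had a Pearson r of 0.76 and a Spearman rho of 0.75.

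Probes differ in affinity, so signals of different miRNAs do not rank their abundance. The brightest probes in total BM were those for miR-1224 (8679 ± 655 intensity units, with the error deposited for that signal), miR-223 (7250 ± 641), miR-15b (3559 ± 321), miR-709 (3130 ± 278) and miR-720 (2647 ± 228). In LKS cells they were those for miR-720 (2594 ± 218), miR-92a (2052 ± 191), miR-20a (1966 ± 171), miR-15b (1481 ± 135) and miR-19b (1368 ± 127). The name miR-720, among the brightest on both arrays, matched no RefSeq miRNA gene. MiR-92a, miR-20a and miR-19b belong to the miR-17-92 cluster and its paralogs, which are known to act in proliferating cells.

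Among the 93 miRNAs detected on both arrays, 17 were at least 2-fold higher in LKS cells, 17 were at least 2-fold lower, and 59 lay within 2-fold. All 34 of these differences exceeded 2 technical errors of their log2 ratio. This followed largely from the 2-fold rule, since the median error of a log2 ratio was 0.19, and it does not bear on the scaling. The largest LKS excess was that of miR-196b, which is encoded in a Hox gene cluster: its signal was 164 ± 15.4 in LKS cells and 9.78 ± 2.997 in total BM, a 27.7-fold scaled difference (log2 ratio 4.79 ± 0.46). MiR-99a was 15.1-fold higher, miR-130a 14.5-fold, miR-542-5p 7.62-fold, miR-126-3p 5.98-fold, miR-181c 5.27-fold and miR-155 4.26-fold. These 7 were also the only ones at least 2-fold higher in the signals as deposited. The next were miR-181d (3.12-fold, from faint signals of 15.3 ± 3.08 and 8.12 ± 2.94), miR-221 (2.61-fold) and let-7c (2.58-fold). The differences of these without scaling were below 2-fold. The balance of the counts depended on the scaling. Unscaled signals gave 7 higher and 36 lower, the authors' deposited value table gave 7 and 28, and median scaling gave 22 and 14. Quantile normalization gave 29 and 14, and scaling on 6 non-miRNA probes, added after the data were seen, gave 11 and 21. These probes were taken as controls because they carry no miRNA identifier, and the files do not define most of them.

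**Figure D1:**
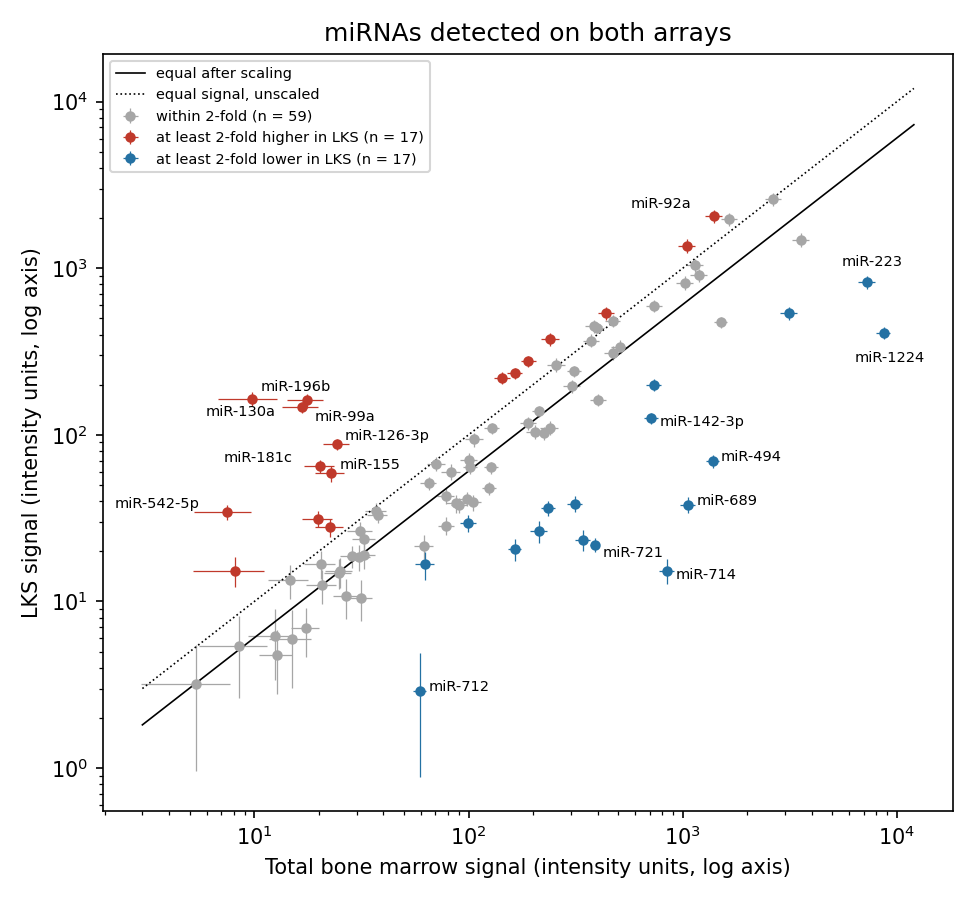
Signal on the total bone marrow array (x axis) against the LKS array (y axis), both in intensity units on log axes, for the 93 miRNAs detected on both; bars are the deposited errors of each signal, the solid line marks equal levels after scaling and the dotted line equal unscaled signal. The 17 miRNAs at least 2-fold higher in LKS cells include miR-196b, miR-99a and miR-130a, and the 17 at least 2-fold lower include miR-714, miR-1224 and miR-223.

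Among the 5 miRNAs detected in LKS cells only were 3 that sit with miR-99 family members in conserved miR-99/let-7/miR-125 clusters. Let-7e had a signal of 40.2 ± 4.85 in LKS cells and 1.30 ± 2.87 in total BM, at least 9.42-fold higher. MiR-125b-5p, known to expand haematopoietic cells when overexpressed, had 26.7 ± 3.95 and 0.116 ± 2.86, at least 7.56-fold higher. MiR-125a-5p had 5.43 ± 2.80 and -1.31 ± 2.85, with a bound of 2.04-fold. MiR-193b had 7.13 ± 2.81 and 0.122 ± 2.85, with a bound of 2.02-fold. These 2 bounds leave out the error of the LKS signal. The unscaled differences were only 1.69 and 1.75 combined errors, so neither excess is clear of noise. The bound for miR-101a was 1.20-fold (10.2 ± 2.81 against 8.20 ± 2.91). Its 2 signals differed by less than either error and gave no bound above 1 without scaling, so this excess is not clear of noise either. Without scaling, the bounds for let-7e and miR-125b-5p were 5.71-fold and 4.58-fold, and those for miR-125a-5p and miR-193b were 1.24-fold and 1.23-fold. Of the 7 members of the cluster list, miR-99a and let-7c were detected on both arrays and higher in LKS cells, and miR-99b and miR-100 were not detected on either array.

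The list of 11 stem and progenitor miRNAs from published work had a higher signal in LKS cells for every member. Its 7 members detected on both arrays (miR-155, miR-99a, miR-126-3p, miR-196b, miR-130a, miR-542-5p and miR-181c) were all at least 2-fold higher, with log2 ratios from 2.09 to 4.79 and a median of 2.93. The other 4, miR-125b-5p, miR-125a-5p, miR-193b and let-7e, were detected in LKS cells only. For miR-125a-5p and miR-193b the unscaled difference was below 2 combined errors (1.69 and 1.75). The list's median lay at percentile 99.9 among random lists. Members of this list may have been selected on these very samples, so it is not independent evidence of its direction.

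Other clusters and families were less uniform. Both detected members of the Hox cluster list were higher in LKS cells, miR-196b as above and miR-10a by 2.52-fold, while miR-10b, miR-196a and both arms of miR-615 were not detected. In the X-linked cluster of miR-322, miR-542-5p was 7.62-fold and miR-322 2.35-fold higher, whereas miR-503 had a log2 ratio of -0.61 ± 0.78. The median of these 3, 1.23, lay at percentile 95.5. The other 6 names of this list, among them miR-542-3p, were detected on neither array. Of miR-221 and miR-222, both known to target Kit, miR-221 was 2.61-fold higher in LKS cells and miR-222 was not detected. In the list of endothelial and megakaryocytic miRNAs, used as markers of other cell types, miR-126-3p and miR-130a were higher in LKS cells, and both also stand in the stem and progenitor list. MiR-126-5p was not detected.

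Some miRNAs known from mature blood cells were lower in LKS cells, while the myeloid list as a whole did not stand apart. All 3 erythroid miRNAs were detected in total BM and not in LKS cells. MiR-451 had a signal of 260 ± 19.4 in total BM and 3.67 ± 2.72 in LKS cells, at least 17.3-fold lower in the latter. The bounds were at least 6.71-fold for miR-486 and at least 3.67-fold for miR-144. MiR-223, abundant in neutrophils, was 5.34-fold lower in LKS cells (822 ± 73.0 against 7250 ± 641). The other 4 members of the mature myeloid list detected on both arrays lay within 2-fold after scaling: miR-21 had a log2 ratio of 0.33, miR-24 of 0.35, miR-23a of -0.42 and miR-27a of -0.58. The list median of -0.42 lay at percentile 13.7. Without scaling it was -1.14, and miR-23a and miR-27a, at -1.14 and -1.31, were also over 2-fold lower. MiR-146a was detected in total BM only, with a signal of 12.6 ± 3.11 that gives no bound above 1, and miR-146b on neither array.

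Both arms of miR-142, a miRNA expressed throughout the blood system, were lower in LKS cells, miR-142-5p by 3.91-fold and miR-142-3p by 3.42-fold, a direction that turned only when arrays were scaled on all miRNAs, detected or not. In the lymphoid list, miR-342-3p was 4.94-fold lower, and miR-150, high in mature lymphocytes, was detected in total BM only (17.7 ± 3.22, at least 3.69-fold). MiR-181d was 3.12-fold higher (log2 ratio 1.64 ± 0.60, and 0.92 without scaling). This came from faint signals of 15.3 ± 3.08 in LKS cells and 8.12 ± 2.94 in total BM, the latter under 3 times its error. MiR-181a and miR-181b had log2 ratios of -0.01 ± 0.31 and 0.54 ± 0.22. The median of the 4 members measured on both arrays, 0.27, lay at percentile 78.5 and became -0.46 without scaling.

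Among miRNAs detected on both arrays, those with the largest deficits in LKS cells were not in blood cell lists. MiR-714 was 33.4-fold lower (15.3 ± 2.63 against 845 ± 70.0), miR-689 16.9-fold, miR-1224 12.8-fold, miR-494 12.0-fold, miR-721 10.7-fold and miR-574-5p 8.83-fold. MiR-712 was also among the 10 lowest, but its LKS signal of 2.91 ± 2.02 was the lowest detected on the array, and its log2 ratio of -3.62 ± 1.01 became -2.18 with recentred background and -2.71 in the authors' deposited value table. After these came miR-223, miR-342-3p and miR-22 (4.86-fold). Of these names, miR-714, miR-689 and miR-712 matched no RefSeq miRNA gene. Probe sequences were not used here, so GC content and cross-hybridisation were not examined for any of these probes. The 5 brightest of the 52 miRNAs detected in total BM only were miR-801 (at least 49.8-fold), miR-188-5p (58.9-fold), miR-451 (17.3-fold), miR-705 (43.5-fold) and miR-671-5p (41.5-fold). MiR-801 also matched no RefSeq gene. The bound was at least 2-fold for 38 of these 52.

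Most members of broadly expressed families lay within 2-fold, and the sign of the medians of the miR-17-92, miR-29 and miR-30 groups depended on scaling. The median log2 ratio of 8 let-7 family members was 0.73 after scaling and 0.00 without it, at percentile 92.3. Let-7c and let-7b were 2.58-fold and 2.03-fold higher in LKS cells, let-7d and let-7a had log2 ratios of 0.94 and 0.75, and miR-98 was lowest at 0.00. Of 9 members of the miR-17-92 cluster and paralogs, miR-92a and miR-19b were 2.42-fold and 2.16-fold higher and 7 lay within 2-fold, among them miR-20a at 0.98 and miR-20b at 0.86. Their median was 0.49 at percentile 75.1, and -0.23 without scaling. In the miR-15/16 family, miR-16 was 2.21-fold lower, miR-15a and miR-15b had log2 ratios of -0.95 and -0.54, and miR-322 was higher as above. MiR-195 and miR-497 were detected in total BM only, at signals of 5.61 ± 2.94 and 6.98 ± 2.94. The family median of -0.74 lay at percentile 11.1, and was -1.47 without scaling. All members of the miR-29 and miR-30 families lay within 2-fold, with medians of 0.40 at percentile 82.4 and -0.00070 at percentile 64.0. Without scaling these medians were -0.33 and -0.72.

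**Figure D2:**
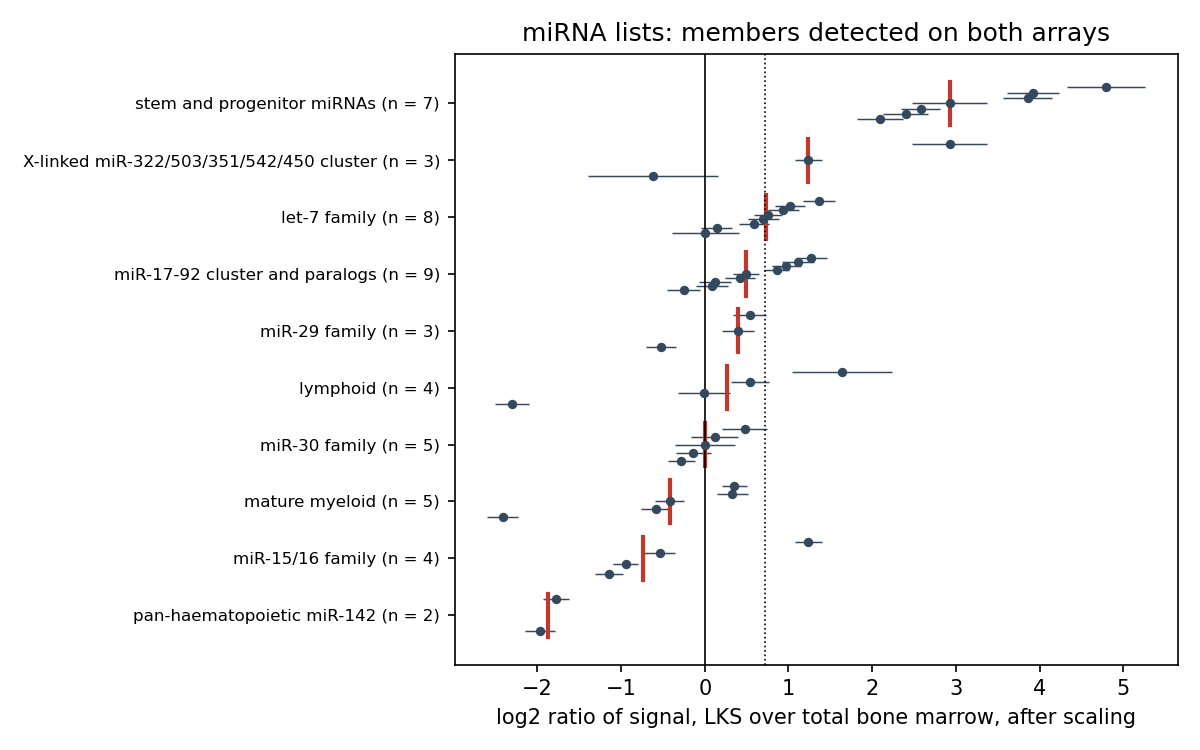
Scaled log2 ratio of signal, LKS over total bone marrow (x axis), for the members of each list detected on both arrays (y axis); points are miRNAs, bars their technical errors, red ticks list medians, the solid line no difference after scaling and the dotted line no difference in unscaled signal. The 7 stem and progenitor members lie between 2.09 and 4.79, and the miR-142 arms lie at -1.97 and -1.77.

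MiRNAs of other tissues were mostly undetected. None of the 6 mesenchymal stroma miRNAs on the array and none of the 9 muscle, liver and neuron miRNAs was detected in either sample. Of 7 epithelial miRNAs, miR-200c was detected, in total BM only (17.8 ± 3.48, at least 3.71-fold). Of 52 probes for miRNAs of the imprinted Dlk1-Meg3 region, 47 were detected on neither array. MiR-494 was 12.0-fold lower in LKS cells, and miR-370 (134 ± 10.5), miR-134 (31.6 ± 2.57), miR-341 (12.3 ± 2.98) and miR-770-3p (11.8 ± 2.12) were detected in total BM only. With 416 names below detection, a miRNA absent from these counts was not detectable at this signal rather than shown to be missing.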

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

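Viral and control probes were flagged where they carried a detection call; 6 of the control probes also served for 1 of the scalings above. The tests in this part were chosen after the values had been seen, except that computing the ratios without scaling had been decided before the data were examined. One of 10 probes for murine gammaherpesvirus miRNAs, mghv-miR-M1-2, was detected on both arrays, at 43.8 ± 3.03 in total BM and 16.04 ± 2.08 in LKS cells. The other 9 viral probes were detected on neither array.

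The control probes hur_1, hur_2, hur_4, hur_6, mr_1 and a bright corner probe, of which the files do not define the hur and mr names, were detected on both arrays. In total BM and LKS cells, respectively, hur_1 read 20829 and 13918, hur_2 382150 and 295030, hur_4 3800 and 1874, hur_6 39243 and 26017, mr_1 24508 and 20348, and the corner probe 568 and 429. Every one was dimmer on the LKS array, with a median log2 ratio of -0.49.

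The first pattern weighed is the set of 52 miRNAs detected in total BM only. A dimmer LKS array would leave their LKS signals near the total BM signal times the brightness ratio. With each array's background offset allowed for, 40 of the 52 (76.9%) lay over 2 combined errors below that level and 25 over 5. The 52 were selected for not being detected in LKS cells, which favours shortfalls. The control probes and the viral probe dimmed by unequal factors, from 1.20 (mr_1) to 2.73 (mghv-miR-M1-2), so 1 ratio for all probes does not hold. With 2.73 applied to every probe, 32 of the 52 still lay over 2 combined errors below and 21 over 5. At these factors uniform dimming thus leaves most of the set short by 2 combined errors. The selection of the set adds to that count by an amount not measured here, and dimming by other factors at single probes stays open. Names with no RefSeq miRNA gene made up 5.77% of the set (3 of 52: miR-712*, miR-715 and miR-801), so such names do not account for it. A RefSeq match does not show that a name still stands as a miRNA, so withdrawn names with a listed gene stay open. Whether probes with a listed gene catch other RNAs was not tested. All 3 erythroid list members lay in the set, consistent with mature cells that the sort removes, a hypothesis that this bears on for those 3 only.

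The second pattern is the LKS excess of the 11 published stem and progenitor miRNAs. Scaling does not account for it: the lowest log2 ratio among the 7 shared members was 1.37 with no scaling. Nor does noise near detection for most members, since 9 of 11 had an unscaled difference above 2 combined errors, the exceptions being miR-125a-5p (1.69 combined errors) and miR-193b (1.75). Variation between animals or preparations stays open, because each group is 1 array, and the list may have been picked on these samples.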

How the results depend on the processing

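No paired analysis was possible because each group has 1 array, and no array could be left out in turn. The main counts were 17 higher and 17 lower in LKS cells. Scaling on the 75th percentile of all miRNAs gave 77 and 7. That percentile was 8.0 on total BM and 1.12 on LKS, the latter below the lowest detected LKS signal (2.91). This scaling alone turned the direction of named miRNAs at least 2-fold apart: the log2 ratios became 0.34 for miR-142-3p, 0.15 for miR-142-5p, 0.97 for miR-16 and 0.30 for miR-709. No scaling gave 7 and 36, the deposited values gave 7 and 28, quantile normalization 29 higher, and scaling on the non-miRNA probes 11 higher. A threshold of 1.5-fold gave 28 and 27, and one of 4-fold 7 and 11. Counting miRNAs detected on at least 1 array gave 57 lower with the planned floor for undetected signals (the lowest detected signal of the array, or the probe's own signal if higher) and 55 with the floor used for bounds, all miRNAs with signal above 0 gave 39 lower, and the brighter part of the shared miRNAs 7 higher. Requiring a signal above the highest negative control or viral probe left 64 detected in total BM and 43 in LKS cells. The percentiles of lists cannot change under scalings that add 1 constant, and that of the stem and progenitor list is near its ceiling, so its values of 99.9 to 100 say little of stability. The X-linked cluster passed the central 95% under loess (97.7) and with the planned floor (97.9), but not with the floor used for bounds (97.44). Both floors left its 3 members and their median of 1.23 unchanged, so only the random lists differed there. With the planned floor and that of the bounds, respectively, the cluster list of miR-99, let-7 and miR-125 lay at percentiles 100 and 99.97, the Dlk1-Meg3 list at 0.625 and 0.565, and the erythroid list at 4.98 and 4.18. All detected members of that cluster list except let-7c also stand in the stem and progenitor list. Its percentile is thus not separate evidence, and its members detected in LKS cells only enter with a floor for total BM. Likewise, 4 of the 5 detected Dlk1-Meg3 members and all 3 erythroid members were detected in total BM only and enter with a floor for LKS. The low side of these 2 lists was therefore largely set by the detection calls, and their percentiles are not measured shifts. Of 29 named miRNAs at least 2-fold apart, 21 stayed so without scaling and 29 with recentred background. Control-probe scaling, recentring, list percentiles and counts with the floor of the bounds, the error filter and the RefSeq filter were added after seeing the data. The cause of the shifts was not tested.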

Other observations

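The tests on neighbouring genes whose names match 1 gene and on hairpin arms were planned before their results were seen; the other comparisons here were chosen after seeing the values. Members of 1 miRNA cluster were not always detected together. MiR-20a read 1650 ± 144 and 1966 ± 171 in total BM and LKS cells, while miR-17 from the same cluster was not detected (7.66 ± 2.91 and 4.57 ± 2.73), although its star arm miR-17* was detected on both arrays and was 2.04-fold higher in LKS cells. MiR-106a was likewise undetected while its neighbour miR-20b read 399 ± 29.4 and 438 ± 32.6. By the detection calls, the arms of miR-125a were detected on opposite arrays: miR-125a-3p in total BM only (41.2 ± 3.95, at least 8.57-fold) and miR-125a-5p in LKS cells only, the single such pair. The 5p signals were 5.43 ± 2.80 in LKS cells and -1.31 ± 2.85 in total BM. They lay only 1.69 combined errors apart, so the LKS side of this pair is uncertain.

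MiRNAs with name numbers from 670 to 770 were found mostly on the total BM side. They made up 5 of the 17 at least 2-fold lower in LKS cells, 15 of the 52 detected in total BM only and 2 of the other 81 detected miRNAs. Those 81 include the 17 at least 2-fold higher in LKS cells, of which 0 had such a number. The number range was chosen after the values were seen.

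Neighbouring miRNA genes may share their difference between the samples, as transcription from 1 primary transcript would give. Over 18 pairs of shared miRNAs with genes within 10 kb in RefSeq, leaving out names that match several genes, the median absolute difference of log2 ratios was 0.51, against 1.26 when ratios were assigned at random, at percentile 1.17. With such names included there were 45 pairs, with a median of 0.42 against 1.25 at percentile 0.01, among them miR-99a and let-7c, which differed by 2.55. The pairs overlap within clusters, and neighbours can have similar sequences, so cross-hybridisation stays open. Ratios were reassigned, here and for the hairpin arms below, among all 93 shared miRNAs without matching on signal. Many pairs had both ratios within 2-fold. The percentiles of the pairs therefore cannot tell a shared transcript from membership in clusters with small ratios. The widest gap in either set was between miR-503 and miR-542-5p (3.54). For the 3 hairpins with both arms detected on both arrays (miR-140, miR-142 and miR-30b) the median difference was 0.19, against 1.24, at percentile 2.24.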
